A study of Homo sapiens with 27 samples.

How the data were processed

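Gene expression was measured in LS174T human colorectal carcinoma cells with a doxycycline-inducible mouse Snail1-HA transgene (the SNAI1 line) or a mouse Lef1-HA transgene (the LEF1 line), and in a control line. Per the labels' protocols, doxycycline was given at 0.1 µg/ml and renewed at 48 h. RNA was extracted with the PeqGOLD kit and turned into biotinylated cRNA (Ambion MessageAmp kit) for Illumina bead arrays. The 27 arrays form 18 groups of line and time, 9 with 2 arrays and 9 with 1. The control line had 9 arrays (2 at 0 h and at 6 h, 1 each at 3, 24, 48, 72 and 96 h), the SNAI1 line 11 (2 at 0, 6, 48 and 96 h, 1 at 3, 24 and 72 h) and the LEF1 line 7 (2 at 0, 6 and 72 h, 1 at 24 h). One array of the LEF1 line is titled 6 h but carries 0 h in its time field; it was taken as 6 h. The labels do not say whether replicates came from separate cultures.

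The authors deposited a table of probe intensities on a log2 scale that were not normalized between arrays, with a detection p-value per probe and array. Per the file headers this column is the detection p-value, and the log2 scale was read from the values. A matrix of log2 values deposited by the authors is quantile normalized over the 27 arrays and keeps each array's rank order. Scanner software, summarisation and any background step are not given in the sources used here.

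The form of the detection p splits the arrays into 2 sets. The 18 arrays of set 1 (all 11 of the SNAI1 line and 7 of the control line) have continuous p-values, 18241 to 19683 detected probes and median log2 intensities from 6.71 to 6.87. The 9 arrays of set 2 (all 7 of the LEF1 line, control line 0 h replicate 2 and control line 6 h replicate 1) have stepped p-values, 14766 to 15918 detected probes and medians from 6.49 to 6.59. The control line's pairs at 0 h and 6 h span the sets. Across genes, which are not independent replicates, these pairs correlated at 0.960 and 0.976, the 4 pairs of the SNAI1 line at 0.983 to 0.991 and the 3 pairs of the LEF1 line at 0.976 to 0.980.

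Intensities were background corrected with normexp, with negative controls inferred from the detection p, and quantile normalized with an offset of 16 (neqc of limma 3.58.1 in R 4.3.3). Of 47323 probes, 32 with missing or infinite values were dropped, 30092 map to 1 gene, 8 to several and 17191 to none. Probes with a detection p under 0.01 on at least 2 arrays were kept (25629), and the probe with the highest mean stood for each gene, which left 13510 genes. The files name no genome build, so no coordinates are given.

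A limma model with 1 mean per group was fitted, with 9 residual and 4.92 prior degrees of freedom. Groups with 1 array take their spread from the groups with 2. Times were weighted equally. The late effect of the SNAI1 line is the change from 0 h averaged over 24, 48, 72 and 96 h minus the same change in the control line, its early effect uses 3 and 6 h, and the late effect of the LEF1 line uses 24 and 72 h. The other contrasts were late minus early in the SNAI1 line, the LEF1 line at 6 h, the SNAI1 minus the LEF1 line over 24 and 72 h, each line against the control line at 0 h, and the control line late against its 0 h. P-values were adjusted by Benjamini and Hochberg's method at 5% over the 13510 genes of each of the 9 contrasts.

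The 18 gene lists were fixed before the data were examined: epithelial junction genes, epithelial regulators and keratins, mesenchymal genes, Wnt/beta-catenin targets, Eph receptors and ephrins, G1/S and DNA replication genes, G2/M and mitosis genes, cell cycle inhibitors and p53 targets, goblet and secretory markers, enterocyte markers, invasion, matrix and integrin genes, Notch, BMP and TGF-beta response genes, ATF4 stress response genes, hypoxia and glycolysis genes, cholesterol synthesis genes, interferon response genes, markers of other cell types, and reference genes. Each was tested against all other genes with camera at a preset correlation of 0.01, adjusted over all 162 tests, and again with an estimated correlation and with fry.

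Named genes follow a rule also set before the data were examined: per contrast the 8 genes with the largest rise and the 8 with the largest fall past the 5% threshold with the same sign at every time point (5 and 5 for the 0 h and control contrasts), up to 4 members per list with the lowest adjusted p, and the genes SNAI1, LEF1, CDH1, EPHB3, AXIN2, MYC, VIM, ZEB1 and CDKN1A. No named gene had another probe past the threshold in the other direction. Where a probe was not detected on any array of one side of a change within a line (late, or 0 h or 3 and 6 h), a fold is given as a lower bound from that line's own arrays, with the late times weighted equally.

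The same steps were checked on simulated data: of 100 genes changed by 2 on the log2 scale, 86 were called in the SNAI1 line late, 73 early, 63 in the LEF1 line late, 73 in it at 6 h and 70 in the difference of the lines, and of 100 changed by 1, 9, 4, 2, 6 and 8. A list of 18 genes shifted by 1 was called in all 5 comparisons with either correlation, and none of the 17 other lists was. The simulated genes varied independently of one another, so this cannot show whether the preset correlation is right for the real lists. Replicate numbers were checked for pairing by correlating, across genes, the differences between replicates 1 and 2 of each pair of groups. The 3 correlations within the LEF1 line were 0.471 to 0.523, and the other 33 ran from -0.435 to 0.148 (5 over 0.1). The LEF1 line's replicate number was therefore tried as a block. Other alternatives were the authors' matrix, other background, scaling, filter and probe choices, limma's trend and robust options, other baselines, each array left out, and, chosen after seeing the data, array set as a block or within-set fits. Within either set the control line has 1 array per time, so its spread comes from other groups. Lists within sets were tested at the preset correlation only. All 27 arrays were used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.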

Results

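Expression of the mouse Snail1 transgene for 24 h or longer lowered genes of the colonic epithelial program in LS174T cells. It raised LEF1, which encodes a partner of beta-catenin at Wnt target genes, together with the Wnt inhibitor genes NOTUM and APCDD1 and the matrix gene VCAN. The mouse Lef1 transgene raised NOTUM and APCDD1 too, and VCAN read higher late in that line as well. It did not shift the fixed lists of junction genes and epithelial regulators past the threshold. Goblet, enterocyte and cholesterol synthesis lists were lower late in both lines at the preset correlation. No list test in either line held with an estimated correlation. Adjusted over all 13510 genes, nothing passed in either line at 3 or 6 h. The question addressed is which part of the response to SNAIL1 is also seen when LEF1 alone is induced.

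In the SNAI1 line the human LEF1 gene was 23.1-fold higher late than at 0 h, relative to the control line (log2 change 4.53, SE 0.483, adjusted p = 4.08e-05 in limma). Its change grew from 0.11 at 3 h to 0.54 at 6 h, 2.66 at 24 h and 4.72 at 48 h. CDH1, which encodes the adherens junction protein E-cadherin, fell 2.66-fold (log2 change -1.41, SE 0.241, adjusted p = 0.00182), with -0.63 at 24 h and -2.06 at 96 h. EPHB3, which encodes a receptor that keeps crypt cells in place, fell 13.6-fold (log2 change -3.77, SE 0.669, adjusted p = 0.00241). Within array set 1 its change was -3.61 and its adjusted p 0.0631. MYC, a Wnt target and growth regulator, fell as well (-1.28, SE 0.204, adjusted p = 0.00114), but a second MYC probe did not pass over all probes (-0.92, adjusted p = 0.292). AXIN2, a negative feedback gene of the Wnt pathway, did not pass the threshold (0.98, SE 0.317, adjusted p = 0.0737). Among planned settings it passed with the authors' values or no background correction (0.038 each), normexp at offset 50 (0.0389), and trend and robust (0.0317). Against the line's own 0 h (0.00144) and against the control line at the same times (0.000175) it passed too. The other planned settings, single arrays left out aside, did not call it. It passed with array set as a block (0.00865) and within array set 1 (0.0217). VIM, which encodes the mesenchymal filament vimentin (-0.08, adjusted p = 0.912), and CDKN1A, which encodes the cell cycle inhibitor p21 (-0.50, adjusted p = 0.596), were not called. A second VIM probe was detected on 4 of the 27 arrays, all late SNAI1 line arrays (5.01 at 48 h, 6.44 at 72 h, 5.94 and 4.86 at 96 h), and its late change did not pass over all probes (0.81, adjusted p = 0.272). The human SNAI1 probe (4.18 to 4.67 on the log2 scale) and the ZEB1 probe (4.20 to 4.76) were not detected on any of the 27 arrays. Neither the transgene, which is of mouse sequence, nor ZEB1 could therefore be followed.

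**Figure D1:**
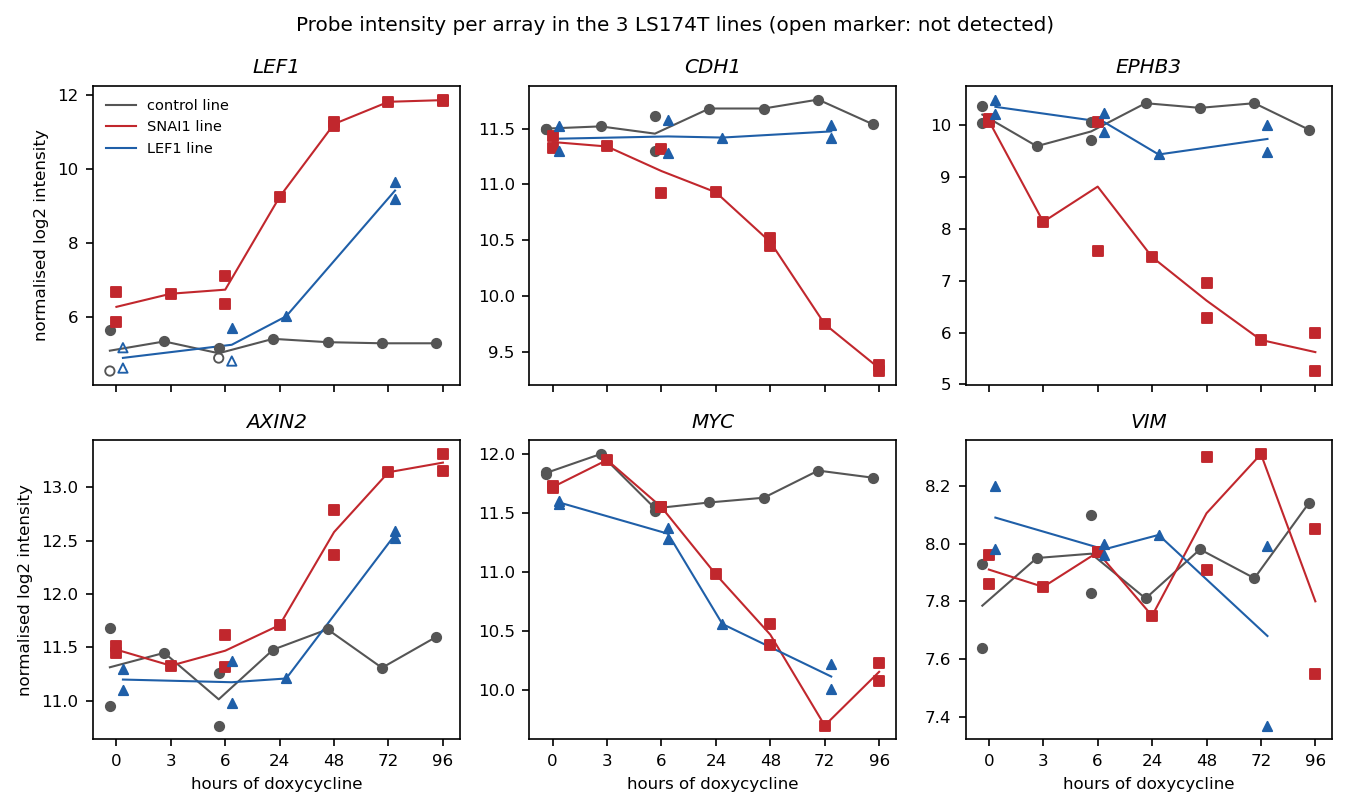
Normalised log2 intensity of LEF1, CDH1, EPHB3, AXIN2, MYC and VIM on each of the 27 arrays (points; open where the probe was not detected) against hours of doxycycline, drawn at even steps, with lines through the means of the control, SNAI1 and LEF1 lines. LEF1 rises in the SNAI1 line by 24 h (log2 change 2.66 against the control line) and in the LEF1 line mainly at 72 h (4.33), while CDH1 falls in the SNAI1 line (-2.06 at 96 h) and not past the threshold in the LEF1 line.

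VCAN, NOTUM and SERPINE2 were among the largest late rises in the SNAI1 line. VCAN encodes the matrix proteoglycan versican (log2 change 5.98, SE 0.529, adjusted p = 1.38e-05). Its mean log2 value also rose in the LEF1 line, from 5.74 at 0 h to 7.74 at 24 h and 9.23 at 72 h. In the control line it was 6.1, 5.69 and 4.87 at these times. NOTUM, which encodes an extracellular enzyme that inactivates Wnt ligands, rose by 5.06 (SE 0.361, adjusted p = 3.19e-06) and was detected on 1 of the 2 arrays at 0 h. SERPINE2 encodes a secreted protease inhibitor (4.57, SE 0.845, adjusted p = 0.00315). LAMP5, a lysosomal membrane protein gene, and SLC40A1, which encodes the iron exporter ferroportin, were not detected at 0 h. They ended at least 27.8-fold and 21.2-fold higher (adjusted p = 6.6e-08 and 1.38e-05). DDIT4L, S100A3 and the pseudogene GRM5P1 rose by 5.61, 4.65 and 4.62.

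CLDN3, which encodes a tight junction claudin, fell in the SNAI1 line by 5.31 on the log2 scale (SE 0.613, adjusted p = 7.85e-05) and was detected on 3 of the 6 late arrays. GPX2, which encodes the epithelial glutathione peroxidase, fell by 5.07 (SE 0.249, adjusted p = 6.6e-08). It differed from 0 h by less than its error at 6 h (-0.21, SE 0.294) and reached -2.22 at 24 h and -6.57 at 96 h. GJB2, which encodes a gap junction connexin (-4.84), and the secreted factors FAM3D (-4.93) and PLA2G3 (-4.59) fell too; late, FAM3D was detected on 1 array of 6 and PLA2G3 on 4. PRR15L (-4.49, adjusted p = 0.0067), LCN15 (-4.48) and the carboxypeptidase-like gene CPXM2 (-4.42, adjusted p = 0.0134) completed the 8 largest falls. PRR15L did not pass within array set 1 (-4.84, 0.0677), and CPXM2 did not without SNAI1 line 0 h replicate 1 (0.071).

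The late effect of the SNAI1 line comprised 1174 genes past the 5% threshold in limma, 526 higher and 648 lower. Of these, 458 and 588 changed at least 2-fold. With array set as a block 1133 passed, 959 of them among the 1174 with the same sign. Within array set 1 alone 1433 passed, 882 of them shared. Leaving out 1 array moved the count to 1917 without control line 0 h replicate 1, 646 without SNAI1 line 0 h replicate 2 and 693 without SNAI1 line 0 h replicate 1.

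Goblet cell and enterocyte genes fell together in the SNAI1 line. Of 27 goblet and secretory markers, 10 passed as lower and none as higher (15 lower when adjusted over the list alone). They were led by ST6GALNAC1, which encodes a sialyltransferase that modifies mucins (-3.84, adjusted p = 2.36e-06). AGR3 and AGR2, which encode disulfide isomerases of secretory cells (-3.45 and -2.19), and DLL1, which encodes a Notch ligand of secretory progenitors (-2.64), followed. Of 16 enterocyte markers 8 were lower and 1 higher (10 and 1 adjusted over the list alone). Among them were VIL1, which encodes the microvillus protein villin (-3.03, adjusted p = 6.09e-06), the adhesion gene CEACAM5 (-3.36) and the carbonic anhydrase gene CA12 (-2.51). Of 24 junction genes 9 were lower and none higher (10 adjusted over the list alone). CLDN7 (-3.13), the polarity gene CRB3 (-2.06) and the desmosomal gene PKP2 (-2.13) fell beside CLDN3. Of 25 epithelial regulators and keratins 13 were lower and 1 higher (17 and 1 adjusted over the list alone). The transcription factor genes EHF (-3.32), CDX1 (-2.62) and FOXA2 (-2.31) were among them. Cholesterol synthesis genes were lower too, 6 of 19 and none higher (10 adjusted over the list alone). TM7SF2, a sterol reductase gene (-3.48), and MVD (-2.04) fell most.

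These 5 lists passed camera with the preset correlation. The goblet list had a median log2 change of -1.45 and an adjusted p = 9.01e-11, the epithelial regulators -1.25 and 8.16e-09, and the enterocyte list -1.39 and 5.85e-06. The junction and cholesterol lists had medians of -0.78 and -0.71 with 2.3e-05 each. In the same order the adjusted p was 0.132, 0.256, 0.161, 0.309 and 0.256 with an estimated correlation. With array set as a block it was 2.65e-13, 3.98e-09, 1.42e-06, 1.45e-05 and 2.93e-06 at the preset correlation. Within array set 1 it was 5.59e-10, 9.18e-09, 6.89e-06, 4.67e-05 and 6.89e-06. Over all 18 lists and 9 contrasts 52 of 162 tests passed at the preset correlation (19 higher, 33 lower). None held with an estimated correlation.

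Mesenchymal genes shifted up, with 4 of 18 higher and none lower, also adjusted over the list alone. The 4 were COL3A1, which encodes a fibrillar collagen and was at least 9.09-fold higher, CDH11, which encodes a mesenchymal cadherin (3.50), the semaphorin co-receptor gene NRP1 (2.60) and MSN (1.75). The list's median was 0.55 and its adjusted p = 0.000341 (0.168 with an estimated correlation, 0.00168 with array set as a block, 0.0206 within set 1). Wnt targets went both ways: 9 of 28 were higher and 5 lower (10 and 6 adjusted over the list alone). The inhibitor genes APCDD1 (4.32) and DKK1 (at least 8.76-fold) and the transcription factor gene SP5 (3.54) were among the rises. The median was 0.68 and the adjusted p = 0.0315 (0.641 with an estimated correlation, 0.0225 with the block, 0.078 within set 1). Of 27 Notch, BMP and TGF-beta response genes 7 were higher and 2 lower (9 and 3 adjusted over the list alone). The Notch effector HEY1 was at least 7.80-fold higher and the growth factor gene TGFB2 at least 4.24-fold, while HES4 (-2.50) and HES5 (-3.37) fell. This list had a median of 0.31 and an adjusted p = 0.0497 (0.256 with an estimated correlation, 0.0501 with the block, 0.125 within set 1).

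The G1/S list (median -0.46, adjusted p = 0.0096, 1 of 30 genes lower) and the G2/M list (median -0.29, adjusted p = 0.0412) passed at the preset correlation. Limma called 0 of the 32 G2/M genes with either adjustment. Neither list held with an estimated correlation (0.814 and 0.836), with the block (0.234 and 0.3) or within set 1 (0.914 and 0.651). The G1/S median was -0.58 at 48 h, -1.08 at 72 h and -0.24 at 96 h, and the G2/M median -0.69 at 72 h and -0.70 at 96 h. Single genes changed in lists that did not pass. Of 17 Eph receptors and ephrins 3 were higher, including EFNB3 at least 7.88-fold, and 2 lower (adjusted p = 0.15). Of 27 cell cycle inhibitors and p53 targets 5 were higher, including the oxidoreductase gene TP53I3 by 1.54 (0.0758). Of 27 invasion and matrix genes 6 were higher, including the metalloprotease gene ADAM19 by 2.72 (0.154). The ATF4 stress response list had 2 of 25 higher (0.0933), and the interferon list 2 of 28 higher and 4 lower (0.667). Of 11 markers of other cell types 1 was lower, the fibroblast gene FAP at -3.90 (0.845), and that list's median was 0.31 but its mean -0.22. Of the 15 reference genes 1 was lower (0.55). Hypoxia and glycolysis genes, 3 of 28 lower with the enolase gene ENO2 at -2.72, had an adjusted p = 0.171. It was 0.00631 with array set as a block and 0.843 with an estimated correlation. Within set 1, with 1 control line array per time, the median was -0.61 in place of -0.25. There the control line's own late median was 0.68, so a rise in the control line can account for part or all of the gap.

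**Figure D2:**
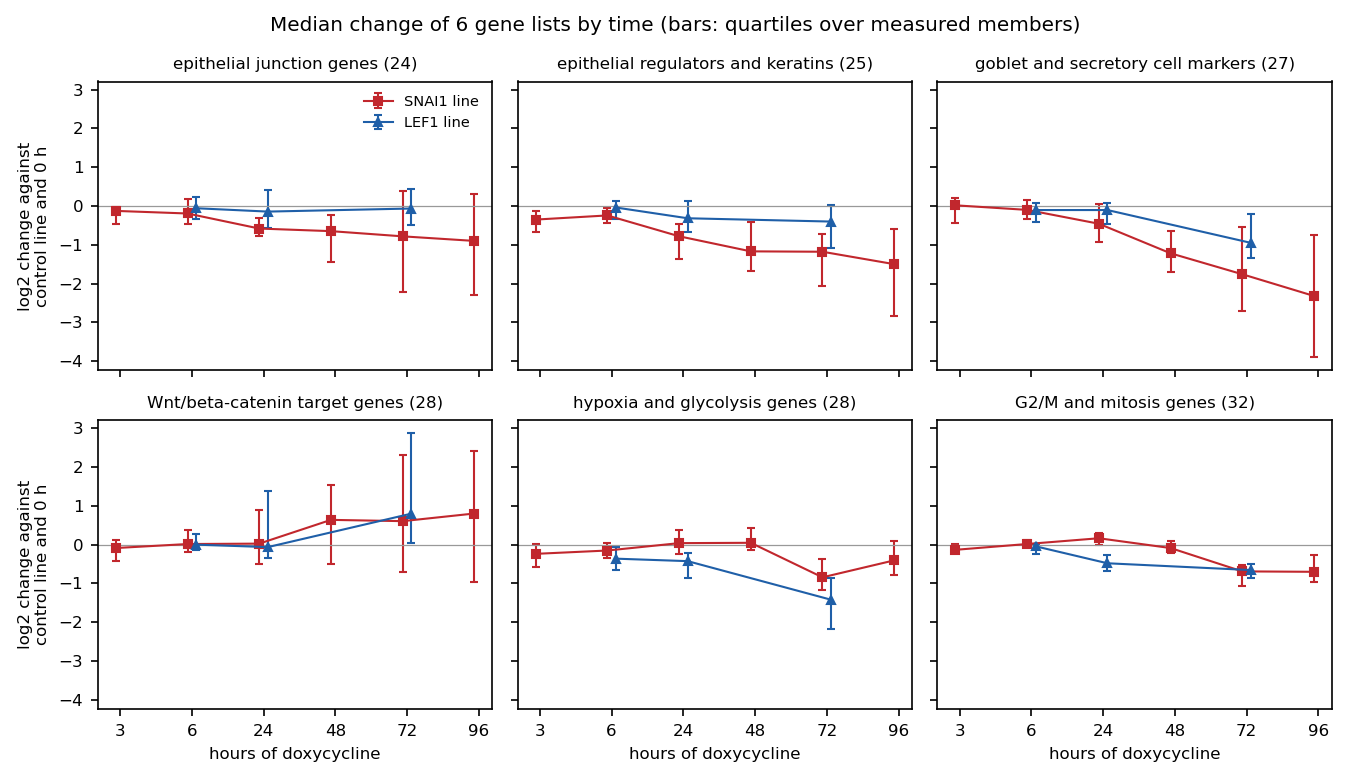
Median log2 change against the control line and 0 h, with bars from the lower to the upper quartile, of 6 gene lists at each time in the SNAI1 line (3 to 96 h) and the LEF1 line (6, 24 and 72 h). The goblet list moves to -2.32 at 96 h in the SNAI1 line and -0.95 at 72 h in the LEF1 line, the epithelial regulators to -1.50 and -0.40, and the hypoxia and glycolysis list to -0.84 and -1.42 at 72 h.

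Epithelial regulators and keratins were lower as a list at 3 and 6 h in the SNAI1 line at the preset correlation (median -0.30, adjusted p = 0.00432, 0.648 with an estimated correlation). The adjusted p was 0.00545 with array set as a block and 0.000311 within set 1. Hypoxia and glycolysis genes were lower too (median -0.18, adjusted p = 0.0231, 0.814 with an estimated correlation). With the block their median was -0.36 (0.000105), and within set 1, where the control line has 1 array at 0 h, it was -0.76. Goblet markers passed as lower only with the block (0.0187) and within set 1 (0.0108). Passing within set 1 alone, G1/S and G2/M genes were higher (medians 0.33 and 0.21, 8.63e-08 and 0.00577), and enterocyte and interferon genes lower (-0.29 and -0.24, 0.0175 and 0.0103). No single gene passed: limma called 0, with 337 at an unadjusted p under 0.05, and 0 with array set as a block or within set 1. Without SNAI1 line 6 h replicate 2 it called 2, PRR15L (-3.42) and the membrane protein gene TMEM125 (-1.88), with an adjusted p = 0.0493 each (0.0808 and 0.0407 with the block). Both are named because they made up that count, after their values were seen. Without SNAI1 line 0 h replicate 1 it called 1. PRR15L read 10.6 on both 0 h arrays, 7.84 at 3 h, and 6.97 and 10.7 on the 6 h arrays. EPHB3 read 7.57 and 10.1 on the 6 h arrays against 10.1 on both 0 h arrays.

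Between the early and the late times the SNAI1 line gained most of its response. LAMP5 (adjusted p = 2.59e-08), the stem cell receptor gene LGR6, the myosin light chain gene MYL10, the growth factor gene FGF19 (4.34) and ANXA1 (4.30) were higher late than early. LAMP5, LGR6 and MYL10, not detected at 3 or 6 h, ended at least 27.6-fold, 19.4-fold and 20.6-fold above these times. GPX2 (-4.92, SE 0.227, adjusted p = 2.59e-08), the fatty acid transporter gene SLC27A2 (-4.32), the potassium channel gene KCNT1 (-4.30) and GPA33, which encodes an intestinal surface antigen (-4.13), were lower. Of 27 goblet and secretory markers 13 were lower and none higher (16 adjusted over the list alone). Their median was -1.55 and their adjusted p = 5.79e-10 (0.132 with an estimated correlation). Wnt targets were higher, 10 of 28 against 3 lower (adjusted p = 0.00442, 0.43 with an estimated correlation). In all 1120 genes passed, 531 higher and 589 lower. The count was 1329 with array set as a block, 1996 with the LEF1 line's replicate number as a block too, and 1876 within set 1. It was 689 without control line 72 h or SNAI1 line 72 h, and 694 without control line 96 h.

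In the LEF1 line NOTUM (4.49, adjusted p = 6.26e-05) and APCDD1 (4.53, adjusted p = 6.26e-05), which both encode inhibitors of Wnt signalling, rose over 24 and 72 h. SLC40A1 was at least 26.6-fold higher (adjusted p = 2.37e-05) and GRM5P1 at least 33.8-fold. DACH1, a transcriptional corepressor gene (5.28, adjusted p = 2.29e-05), the small GTPase gene RASL11B (5.27) and NRP1 (3.50) rose as well. The tripartite motif genes TRIM51 and TRIM48 rose by 6.39 and 5.62, and TRIM49C at least 21.6-fold (adjusted p = 0.00122, 0.00169 and 0.000348). These 10 genes were called with every array left out in turn. The Wnt inhibitor gene DKK4 rose by 4.81 at 24 h and 6.12 at 72 h (adjusted p = 0.00553, 0.144 without control line 72 h). Of 28 Wnt targets 8 were higher and 1 lower (10 and 3 adjusted over the list alone). Their median was 0.45 and their adjusted p = 2.83e-05 (0.256 with an estimated correlation, 1.33e-05 with array set as a block, 5.73e-07 within set 2 against the line's own 0 h).

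Falling genes in the LEF1 line included the alarmin gene IL33 (-3.79, SE 0.529, adjusted p = 0.00237) and MALL, which encodes a raft-associated membrane protein (-3.50, adjusted p = 0.0072). CA12 (-2.53, adjusted p = 0.000348) and the bile acid transporter gene SLC10A2 (adjusted p = 0.00504) fell too. SLC10A2 was detected on none of the 3 late arrays, at least 1.19-fold lower, and did not pass within set 2 (0.112). Without the single control array at 72 h, which leaves 24 h alone, the adjusted p of these 4 rose to 0.212, 0.412, 0.057 and 0.0658. STC1, DDIT4, FXYD3 and FCGR2A were lower as well (-3.29, -3.28, -2.90 and -2.75). Each lost its call when any 1 of 11, 13, 6 and 5 arrays was left out, with adjusted p up to 0.829, 0.641, 0.672 and 0.573 without control line 72 h. With array set as a block DDIT4, FXYD3 and FCGR2A did not pass (0.058, 0.0652 and 0.0606).

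The LEF1 probe itself ended at least 4.43-fold higher in the LEF1 line than at 0 h (adjusted p = 0.0369), with fitted log2 changes of 0.82 at 24 h and 4.33 at 72 h. It lost its call in 11 of the 27 fits that leave 1 array out (0.882 without control line 72 h). MYC fell (-1.14, SE 0.233, adjusted p = 0.0282), with the call lost in 6 such fits (0.626 without control line 72 h) and with the mean of all its probes (0.165). CDH1 (-0.18, adjusted p = 0.867), EPHB3 (-0.99, 0.678), AXIN2 (0.60, 0.573), VIM (-0.29, 0.806) and CDKN1A (-0.92, 0.544) were not called. CDKN1A passed as lower against the control line at the same times, without 0 h (-1.26, 0.0313), but not in other planned settings.

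The late effect of the LEF1 line comprised 156 genes, 120 higher and 36 lower. With array set as a block 192 passed, 130 of the 156 among them. With the LEF1 line's replicate number as a block too the count was 331. Within set 2 against the line's own 0 h it was 258, again with 130 of the 156. The count was 24 without control line 72 h, 88 and 100 without LEF1 line 0 h replicates 1 and 2, and 276 without control line 0 h replicate 1. It was 357 without control line 24 h or LEF1 line 24 h, which leaves 72 h alone.

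Hypoxia and glycolysis genes showed the lowest p among the lists of the LEF1 line. Of 28, 1 was lower, the phosphofructokinase gene PFKFB4 at -1.67, and 8 were when adjusted over the list alone. The median was -0.90 and the adjusted p = 7.2e-11 (0.256 with an estimated correlation, 2.1e-16 with array set as a block, 1.13e-09 within set 2 against the line's own 0 h). PFKFB4 lost its call without control line 72 h (0.759) or LEF1 line 0 h replicate 2, and within set 2 (0.13). G2/M genes shifted down (median -0.55, adjusted p = 4.93e-06, 0.648 with an estimated correlation), although limma called 0 of 32. ATF4 stress response genes (-0.77, 0.000249 and 0.641, 1 of 25 lower) and cholesterol synthesis genes (-0.55, 0.000907 and 0.38, 5 of 19 lower adjusted over the list alone) did as well. So did enterocyte markers (-0.88, 0.00109 and 0.253, 2 of 16 lower and 1 higher) and goblet markers (-0.43, 0.00566 and 0.383, 1 of 27 lower). These 5 lists kept their calls at the preset correlation with array set as a block (adjusted p = 0.000192, 0.000241, 0.000202, 0.000381 and 0.000163) and within set 2 against the line's own 0 h. That last fit has no control line. G2/M genes had a median of -0.39 in it, and -0.44 late in the control line within set 1.

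Epithelial structure did not shift past the threshold in the LEF1 line. Junction genes had a median of -0.11 (adjusted p = 0.776) and epithelial regulators -0.36 (0.0842). The adjusted p was 0.187 for mesenchymal genes, 0.706 for Eph receptors, 0.571 for p53 targets, 0.97 for invasion genes and 0.671 for Notch, BMP and TGF-beta genes. G1/S genes (0.172) and interferon genes (0.393) did not pass, but did within set 2 against the line's own 0 h (0.0308 and 0.00106). Their medians there were -0.27 and 0.42. That fit has no control line, and within set 1 the control line moved the same way late (-0.71 and 0.27). A change shared with the control line therefore cannot be told apart there. Markers of other cell types (0.671) and reference genes (0.271) did not pass.

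At 6 h in the LEF1 line hypoxia and glycolysis genes passed as lower against the control line (median -0.36, adjusted p = 0.000304, 0.641 with an estimated correlation, 4.41e-05 with array set as a block). Within set 2 their median was 0.12 and they did not pass (0.361), so this early change is left open. ATF4 stress response genes were higher (median 0.39, adjusted p = 0.0128, 0.799 with an estimated correlation, 0.0121 with the block) but not past the threshold within set 2 (0.066). G1/S genes were lower (-0.22, 0.0263, 0.826 with an estimated correlation, 0.02 with the block), with a median of -0.67 within set 2 (4.26e-06). Passing only within set 2, G2/M genes were lower (0.0206) and interferon genes higher (0.00891). No single gene passed: limma called 0, with 354 at an unadjusted p under 0.05, 0 with array set as a block and 0 within set 2. It called 1 without control line 0 h replicate 2 or LEF1 line 6 h replicate 1.

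Over 24 and 72 h EMP3, an epithelial membrane protein gene (4.71, SE 0.412, adjusted p = 5.08e-05), MYL10, LIX1L and the protocadherin gene PCDH18 (adjusted p = 6.6e-05) were higher in the SNAI1 line. The last 3 were not detected at 0 h or in the LEF1 line late, and ended at least 18-fold, 14.9-fold and 7.96-fold above 0 h in the SNAI1 line. KCNT1 (-5.20, SE 0.493, adjusted p = 7.57e-05), the neuroserpin gene SERPINI1 (-4.49) and the defensin genes DEFA1B, DEFA6 and DEFA5 (-5.04, -4.91 and -4.56) were lower in it. DEFA1B was detected in the SNAI1 line on 1 of 2 arrays at 0 h and on none at 24 or 72 h. It ended at least 1.81-fold below 0 h there, and its -5.04 is no measured size. In the LEF1 line DEFA1B, DEFA5 and SERPINI1 rose late (adjusted p = 0.00187, 0.00815 and 0.000348), with changes at 24 h of 4.52, 3.25 and 4.20, and DEFA6 did not pass (0.126). SLC27A2 (-4.16) and TM7SF2 (-3.76) fell in the SNAI1 line (-3.80 and -2.91 at 24 h, against -0.21 and 0.50 in the LEF1 line). ST6GALNAC1 differed as well (-2.95), and these 12 genes were called with every array left out in turn. SERPINE2 (5.35), S100A3 (3.80), LGR6 (at least 11.4-fold above 0 h), LAMP5 (at least 15.9-fold), KLK4 (-4.88) and DKK4 (-4.71) were called too. They were not without SNAI1 line 72 h (adjusted p = 0.358, 0.584, 0.308, 0.496, 0.104 and 0.0929), and S100A3 was not without SNAI1 line 0 h replicate 1. CDH1 differed by -1.07 (SE 0.275, adjusted p = 0.0556, 0.0374 with array set as a block). Among planned settings CDH1 passed with the authors' values (0.016), trend and robust (0.0174) and no filter (0.0424), for example. It did not with cyclic loess scaling, arrays set to the same median or the mean of all probes. EPHB3 (-2.66, 0.0981), LEF1 (1.43, 0.267), AXIN2 (0.27, 0.894) and MYC (-0.13, 0.927) were not called. LEF1 did pass with the authors' values or no background correction (1.7, 0.00274 each) and normexp at offset 50 (1.7, 0.00674). Other planned settings, single arrays left out aside, did not call LEF1.

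Junction genes and epithelial regulators were lower in the SNAI1 than in the LEF1 line, 6 of 24 and 4 of 25 with none higher. Their medians were -0.58 and -0.83 (adjusted p = 1.94e-06 and 7.34e-06, 0.256 and 0.383 with an estimated correlation). Goblet markers (4 of 27 lower, -0.52, 0.000249 and 0.256), enterocyte markers (2 of 16, -0.42, 0.0263 and 0.383) and interferon genes (1 of 28, -0.37, 0.0167 and 0.641) were lower too. ATF4 stress response genes were higher, 2 of 25 and 13 adjusted over the list alone (median 1.12, adjusted p = 1.75e-08, 0.38 with an estimated correlation). The gap lay at 72 h (1.13 against -0.93), where the SNAI1 line has 1 array, and not at 24 h (-0.37 against -0.53). In the SNAI1 line this list's median was -0.35 at 48 h and 1.22 at 96 h. Hypoxia and glycolysis genes (0.55, 2.83e-05 and 0.583) and G2/M genes (0.31, 0.0231 and 0.814) were higher, although limma called 0 of 28 and 0 of 32. For G2/M genes the gap lay at 24 h (0.17 against -0.48), with 1 array per line, and not at 72 h (-0.69 against -0.66). Mesenchymal genes (1 of 18 higher, CDH11, 0.58, 0.00201 and 0.244) and Notch, BMP and TGF-beta genes (2 of 27 higher and 2 lower, 0.43, 0.00566 and 0.168) were higher as well. CDH11 lost its call without SNAI1 line 72 h (0.987) or SNAI1 line 0 h replicate 1.

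In all 369 genes differed between the lines, 137 higher and 232 lower in the SNAI1 line. All 369 were also called with array set as a block (490), and adding the LEF1 line's replicate number gave 689. The count was 40 without SNAI1 line 72 h and 638 without SNAI1 line 24 h or LEF1 line 24 h. It was 188 and 208 without SNAI1 line 0 h replicates 1 and 2, and 236 without LEF1 line 0 h replicate 2. The change of each line from its own 0 h lies within 1 array set.

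**Figure D3:**
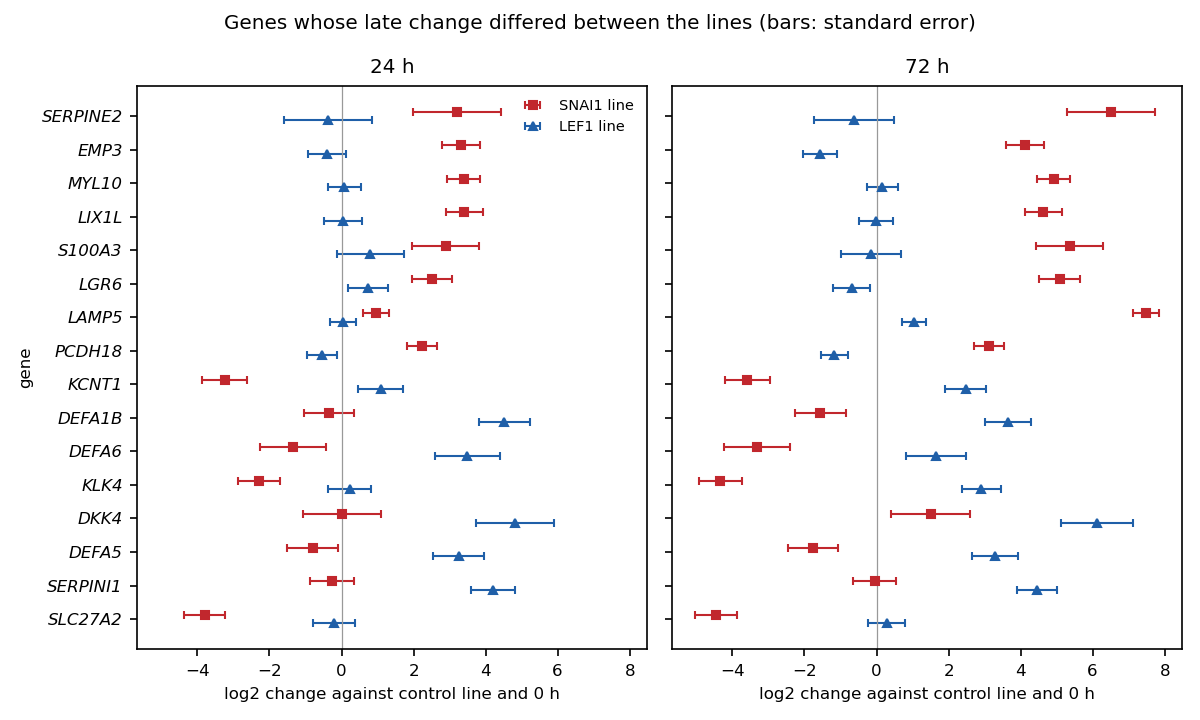
Log2 change against the control line and 0 h, with its standard error as bars, of 16 genes that differed between the lines, at 24 h and 72 h in the SNAI1 and LEF1 lines. DEFA1B changes by 4.52 at 24 h in the LEF1 line and by a fitted -0.35 in the SNAI1 line, where it was not detected at 24 h. SLC27A2 changes by -0.21 in the LEF1 line and -3.80 in the SNAI1 line.

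Genes such as NOTUM, APCDD1, SLC40A1, NRP1 and GRM5P1 rose late in both lines. Over 24 and 72 h 58 genes were higher in both lines (of 252 and 120; 2.24 if the lists were independent) and 16 lower in both (of 327 and 36; 0.871 if independent), with none opposite. Simulated data without any response gave at most 1 and 0, but such data call few genes and so leave little to overlap. Both contrasts subtract the same control arrays, so part of the excess can come from these. Across genes, which are not independent replicates, the changes of the lines correlated at r = 0.555 (Spearman 0.566). Simulated data without a response in either line gave a mean r of 0.517 and at most 0.535 in 100 runs. Lines with real but unrelated responses were not simulated. The covariance was 0.257, against at most 0.101 in simulated data. With array set as a block r was 0.526, below the simulated mean of 0.571, while the covariance of 0.233 lay above the simulated maximum of 0.106. With each line against its own 0 h arrays, where no control array is shared, r was 0.435, against 0.029 at most in simulated data. That comparison keeps any change with time in culture or doxycycline that all lines share. It had 185 genes higher in both lines (21.2 if the calls were independent), 110 lower in both (14.4) and 13 opposite.

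Before induction few genes passed the threshold between either line and the control line. Limma gave 668 genes in the SNAI1 line and 934 in the LEF1 line an unadjusted p under 0.05. The simulated data did not cover these contrasts, so few calls do not show that the lines were alike. EPDR1, which encodes an ependymin-related lysosomal protein, was lower than in the control line in the SNAI1 line (-1.69, SE 0.216, adjusted p = 0.0252) and in the LEF1 line (-1.72, adjusted p = 0.0203). The defensin genes DEFA1B and DEFA5 were higher in the LEF1 line (2.86 and 2.81, adjusted p = 0.0317 each). With array set as a block none of these passed (EPDR1 0.0742 and 0.055, DEFA1B 0.135, DEFA5 0.055). Limma then called 0 genes in either line, with 448 and 982 at an unadjusted p under 0.05. It also called 0 within set 1 for the SNAI1 line and within set 2 for the LEF1 line. The count of 1 in the SNAI1 line became 758 without control line 0 h replicate 1, which leaves only the set 2 array at 0 h, and 3 without SNAI1 line 0 h replicate 2. It became 0 without control line 0 h replicate 2, SNAI1 line 0 h replicate 1, or any array of SNAI1 line 6 h or 48 h or LEF1 line 0 h. The count of 3 in the LEF1 line became 9 without control line 0 h replicate 2 and 1 without either array of SNAI1 line 48 h. It became 0 without control line 0 h replicate 1 or any array of SNAI1 line 6 h or LEF1 line 0 h. In the SNAI1 line the G1/S and G2/M lists were higher (medians 0.47 and 0.36, adjusted p = 1.94e-06 each) and the hypoxia list lower (-0.44, 2.3e-05) at the preset correlation. In that order the adjusted p was 0.0251, 0.000366 and 0.0224 with the block. None of the 3 passed with an estimated correlation (0.646, 0.646 and 0.579) or within set 1, with 1 control line array at 0 h. Cholesterol synthesis genes passed as lower within set 1 (median -0.18). In the LEF1 line G1/S genes were lower (-0.30, 0.00242) and hypoxia genes higher (0.17, 0.0136), but neither passed with an estimated correlation (0.814 and 0.787) or with the block (0.906 and 0.652). With the LEF1 line's replicate number as a further block G1/S genes passed as higher. Within set 2, with 1 control line array at 0 h, G1/S genes had a median of 0.27 and did not pass, while hypoxia genes passed as lower (-0.14). Goblet genes passed as lower and G2/M genes as higher only with the block (0.0403 and 0.0408) and within set 2 (0.00106 and 0.00222).

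In the control line doxycycline and time in culture cannot be separated. Limma called 0 genes late against 0 h, with 531 at an unadjusted p under 0.05, and 0 with array set as a block. It called 3 within set 1 or without control line 0 h replicate 2. Within set 1 this line has 1 array at each time, and list tests measure spread over genes, not over cultures. Lists did shift at the preset correlation. Interferon genes were higher (median 0.26, adjusted p = 0.000249, 0.383 with an estimated correlation, 0.0193 with the block, 0.00106 within set 1). Hypoxia genes were higher (0.25, 0.005 and 0.752), with a median of 0.48 with the block (1.37e-09) and 0.68 within set 1 (1.49e-15). G2/M and G1/S genes were lower (-0.17 and -0.12, 0.00201 and 0.00456, 0.814 each with an estimated correlation). Their medians were -0.36 and -0.48 with the block (4.03e-08 and 2.65e-13) and -0.44 and -0.71 within set 1 (1.13e-09 and 1.63e-19). By time the G1/S median was 0.54 at 48 h and -1.20 at 96 h, and the G2/M median 0.34 and -1.39. Invasion genes passed as higher only within set 1 (0.0123), and ATF4 stress response genes there (0.0139) and with the block (0.0468).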

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

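The tests of SNAI1 line 6 h replicate 2, of array set for the SNAI1 line's late calls, and all fits with array set were chosen only after the results were seen.

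The late response of the SNAI1 line differed from that of the LEF1 line in 369 genes by a test of the difference itself. Each line is set against its own 0 h within 1 array set here, so a constant offset between the sets cancels, but a difference in scale between them could mimic part of this. Within set 1, 75.1% of the SNAI1 line's 1174 late calls were called again with the same sign, and within set 2, against the line's own 0 h, 83.3% of the LEF1 line's 156 were, which argues against array set as the whole cause of either. What stays open is the part of each response outside those shares, and a difference in transgene level between the lines, since the level of the mouse transgenes could not be read here. Of 100 splits of the 10 late arrays of the SNAI1 and control lines, 1, the real one, gave 1174 genes or more, and the highest other gave 711. Other splits can put arrays of different lines or times in 1 group, which raises the spread and lowers the count (median 0). They show that late arrays resemble others of their line, but cannot tell a response from a difference between single cultures.

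Single genes that differed between the lines were SERPINE2 (5.35), EMP3 (4.71), MYL10 (4.04), LIX1L (4), S100A3 (3.80), LGR6 (3.77), LAMP5 (3.67) and PCDH18 (3.53), higher in the SNAI1 line. MYL10, LIX1L, LGR6, LAMP5 and PCDH18 were not detected in the SNAI1 line at 0 h or in the LEF1 line at 0, 24 or 72 h, so their fitted values are no measured size. KCNT1 (-5.20), DEFA1B (-5.04), DEFA6 (-4.91), KLK4 (-4.88), DKK4 (-4.71), DEFA5 (-4.56), SERPINI1 (-4.49) and SLC27A2 (-4.16) were lower in the SNAI1 line. DEFA1B was not detected in that line at 24 or 72 h, so its value is no measured size either. Gene lists that differed, by median log2 change and camera at the preset correlation, were junction genes (-0.58), epithelial regulators and keratins (-0.83), goblet markers (-0.52), enterocyte markers (-0.42) and interferon genes (-0.37), lower in the SNAI1 line, and mesenchymal genes (0.58), G2/M genes (0.31), Notch, BMP and TGF-beta genes (0.43), ATF4 stress response genes (1.12) and hypoxia and glycolysis genes (0.55), higher in it. None of these 10 lists passed with an estimated correlation (adjusted p from 0.168 to 0.814).

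Within the SNAI1 line 1120 genes changed differently late than early, by a test of the difference. The limit given above for such splits holds here too. Of 100 splits of the late arrays 2 gave 1120 genes or more, the real one and 1 that gave 1315. That other split set the 4 late control arrays and both SNAI1 line 96 h arrays against the SNAI1 line's arrays at 24, 48 and 72 h, and so nearly mirrors the real one. The early effect had 10 splits, too few for a share under 5%; the real value was 0 and the highest other 1.

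Epithelial genes such as PRR15L, TMEM125 and EPHB3, low on SNAI1 line 6 h replicate 1, stood near their 0 h level on replicate 2. Over the 1174 late genes, the mean change from 0 h in each gene's late direction was 0.411 on replicate 1 and 0.115 on replicate 2, a share of 0.28, against 0.2 at 3 h. Each 0 h array was scored against the other (0.0366 and -0.0366), so these values do not measure the scatter of a 6 h array. The genes and directions were chosen with the same 0 h arrays as baseline, which can raise the scores of the SNAI1 line. Control line arrays of set 1 scored from -0.0604 to 0.0139. Cells not induced, or a mislabelled array, could give such a value, but so could an earlier point of the response, and these cannot be told apart on 1 array. PRR15L, EPHB3 and TMEM125 read 7.84, 8.14 and 9.035 on the 3 h array and 10.65, 10.07 and 9.771 on replicate 2. For these genes, picked after their values were seen, such a point would lie before 3 h. A dim array would lower raw intensities, yet over the 648 genes lower late the median raw log2 intensity on replicate 2 was 0.0929 above that on replicate 1. Over all genes the median was -0.144 and the upper quartile 0.00871, which argues against a dim array. No biological explanation was tested.

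The LEF1 probe rose late in the line that carries mouse Lef1, 0.82 at 24 h and 4.33 at 72 h. The timing of transgene induction was not measured. If the probe read the transgene, and the transgene were fully induced by 24 h, its change should be near full by then. Its ratio of 24 h to 72 h change was 0.189 and that of a second LEF1 probe 0.223, against a median of 0.426 (quartiles 0.209 to 0.645) over the 356 genes called at 72 h in that line. Against the line's own 0 h the ratios were 0.25 and 0.222, below a lower quartile of 0.281. Neither probe was detected at 0 h in this line, so the ratios rest on an unmeasured baseline, and whether the probes read the mouse transcript cannot be told apart from a rise of human LEF1. Induction of human LEF1 by the transgene was not tested.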

How the results depend on the processing

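Fits with array set, alone or with the LEF1 line's replicate number, within sets, or without SNAI1 line 6 h replicate 2 and with the block were chosen only after seeing the data; the other alternatives were planned. For results without a stated reason, the cause was not tested.

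Of the named genes, 61 of the 72 called in the SNAI1 line late were called in every other setting and 58 with every array left out, 60 and 58 of 70 in late minus early, 16 and 10 of 29 in the LEF1 line late, and 36 and 12 of 46 in the difference of the lines; none reversed. Counts that moved by over 1.5 times follow. The SNAI1 line late (1174) gave 2712 against its own 0 h and 3932 against the control line at the same times. The early effect (0) gave 11 against the control line at the same times and 2 with array set as a block and no second SNAI1 line 6 h array. Late minus early (1120) gave 1996 with both blocks and 1876 within set 1. The LEF1 line late (156) gave 97 with probes detected on all 27 arrays, 53 with only the lines compared, 696 against its own 0 h, 1906 against the control line at the same times, 331 with both blocks and 258 within set 2 against its own 0 h; at 6 h (0) it gave 5 against the control line at the same time. The difference of the lines (369) gave 187 with probes detected on all 27 arrays, which tests fewer genes, and 689 with both blocks. The control line late gave 3 within set 1, against 0.

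At 0 h the SNAI1 line (1) gave 2 with normexp at offset 50, with probes detected on all 27 arrays, with a replicate block and with trend and robust, 4 with both blocks, and 0 with arrays set to the same median, only the lines compared, array set as a block or set 1 only. The LEF1 line (3) gave 1 with no filter and 0 with only the lines compared, array set as a block or set 2 only. Setting arrays to the same median moved the median change of all genes in that contrast to -0.20.

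Of the list tests, 52 passed with camera, 0 with an estimated correlation, 0 with it and array set as a block, and 26 with fry, which does not compare a list with other genes. 1 list test reversed: G1/S and DNA replication genes, LEF1 line against control line at 0 h, were lower with an adjusted p = 0.00242 and higher with both blocks (0.00696). The correlation of the lines' responses (0.555) was 0.435 against each line's own 0 h, where no control arrays are shared, and 0.526 with array set as a block.

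With 1 array left out at a time, where a lone array is assumed to vary like the other groups, counts ran from 646 to 1917 in the SNAI1 line late, 0 to 2 early, 689 to 1624 in late minus early, 24 to 357 in the LEF1 line late, 0 to 1 at 6 h, 40 to 638 in the difference of the lines, 0 to 758 and 0 to 9 at 0 h in the SNAI1 and LEF1 lines, and 0 to 3 in the control line late. The lowest counts of the LEF1 line and of the difference leave 1 time point out. A block for array chips was not run, since the files name no chips. Signal over background limits the SNAI1 and ZEB1 probes, which no array detected, and set 2, where fewer probes were detected than in set 1.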

Other observations

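The test of whether the rise of LEF1 comes first was chosen before its result was seen; the genes in the next 2 paragraphs were chosen for this part only after their values were seen, and fits without single arrays were not examined for GRHL2, OVOL2, ESRP1, KRT19, KRT23, ATOH1 or LGR5, for GPA33 in either line, or for TRIM51, TRIM48 and TRIM49C in the SNAI1 line.

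Regulators that hold cells in the epithelial state fell late in the SNAI1 line beside the junction genes: GRHL2, which encodes a grainyhead factor that maintains epithelial genes (-1.97, adjusted p = 0.0157 in limma), OVOL2, which encodes a repressor of mesenchymal genes (-1.68, adjusted p = 0.0191), and ESRP1, which encodes the epithelial splicing regulator (-1.21, adjusted p = 0.0345, 0.0846 with array set as a block). Among keratins KRT19 fell (-2.03, adjusted p = 0.00703) while KRT23, not detected at 0 h, rose at least 1.83-fold (adjusted p = 0.005). ATOH1, which encodes the factor that commits cells to the secretory lineage, fell at least 6.04-fold to below detection (adjusted p = 0.00456), and so did LGR5, a Wnt target and stem cell marker (-2.16, adjusted p = 0.0294), although other Wnt targets rose. None of these 7 genes passed in the LEF1 line, where the adjusted p was 0.895 for GRHL2, 0.964 for OVOL2, 0.815 for ESRP1, 0.345 for KRT19, 0.983 for KRT23, 0.638 for ATOH1 and 0.406 for LGR5. A direct test of the difference between the lines did not pass for any of the 7 either, with adjusted p from 0.132 (ATOH1) to 0.775 (ESRP1).

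The tripartite motif genes that led the LEF1 line's response also rose in the SNAI1 line: TRIM51 by 4.33, TRIM48 by 4.40 and TRIM49C by 3.95 (adjusted p = 0.00135, 0.000607 and 0.000197). GPA33, which encodes an intestinal surface antigen, fell in both lines (-4.10 and -2.32, adjusted p = 2.37e-05 and 0.0282).

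In the SNAI1 line LEF1 itself had reached 0.493 of its 96 h change at 24 h, so it may drive the genes raised in both lines. If it did, these genes would lag behind those raised in the SNAI1 line alone. The median ratio of 24 h to 96 h change was 0.381 for the 71 genes called as raised in both and 0.418 for the 454 called in the SNAI1 line alone. The difference of -0.0363 (one-sided permutation p = 0.293, 100000 resamples) was in the predicted direction but within what permuted genes give. Of 100 simulated genes changed by 1, only 2 were called in the LEF1 line late, and of 100 changed by 2, 63 were. Some of the 454 may thus be raised in both lines, and the comparison cannot separate these. Single arrays at 24 h leave the order of the responses open.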
